A study of Mus musculus with 28 samples.

How the data were processed

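Spleens of C57BL/6 mice of the transplanted MPLW508A model of primary myelofibrosis, which carries a changed thrombopoietin receptor MPL, were profiled by stranded total RNA sequencing, per the labels' protocols. The 28 libraries, 1 per mouse, fell into 5 groups by their labels: isotype antibody at day 13 (n = 5), at day 20 (n = 5) and at day 34 (n = 8), and the anti-GARP:TGF-β1 antibody 58A2 at day 34 in mice labelled as non-responders (n = 5) or responders (n = 5). Antibody was given at 400 µg per mouse, per the labels' protocols. The series' design text calls the day-13 and day-20 mice untreated while their labels name the isotype antibody, and the labels were followed. The labels do not say by what measure response was defined, nor which Fc form of 58A2 each mouse received, so the responder and non-responder groups are defined by an outcome and not by random assignment.

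The submitters' processing notes name STAR and the GRCm38 build, without a version, and the counting tool and annotation release are not given in the sources used here. Values were deposited in 2 tables that were never merged. The table of days 13 and 20 held whole-number counts per gene symbol as deposited by the authors, with no scaling, for 55367 symbols. The table of day 34 held estimated counts per gene as deposited by the authors, of which 9.17% were fractions, for 55487 gene identifiers, and these were rounded to whole numbers. How reads shared between near-identical genes, such as globins, were assigned, and whether counting used the strand, is not given in the sources used here. Of the day-34 identifiers, 54821 had the same start, end and strand in GENCODE M21, which was used only for this check and for gene types. Total counts lay between 21589253 and 24304697 per library for days 13 and 20 and between 22952198 and 25679424 for day 34, so 1 CPM (the count scaled to library size) stood for 17.9 to 33.3 counts. No 2 libraries of a group agreed within sampling noise (lowest chi-square per degree of freedom 13.7 and 43.2).

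Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, and the quasi-likelihood test with robust dispersion, with Benjamini-Hochberg adjustment at 0.05 and no minimum fold change. The day-20 and day-13 libraries were fitted together, and the 18 day-34 libraries were fitted in 1 model of 3 groups. This left 15463 and 17132 genes to test. Standard errors are those implied by the quasi-likelihood F test. CPM values use the TMM-scaled library sizes. Means are given with the SD over mice.

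The 30 gene lists were fixed before the data were examined and those with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over lists within a comparison. The liver list had too few tested members in either table, and the exocrine pancreas list in the table of days 13 and 20. Beside camera stand the same test with an estimated correlation, the rotation test fry, the count of members past the threshold adjusted over the list alone, and an exact permutation test of a score per library (the mean over members of centred log2 CPM, prior count 2). The last was chosen after seeing the data. With 5 against 5 mice its p cannot fall under 0.00794, so a single list cannot pass after adjustment. Genes were named by a rule fixed before the data were examined: 15 fixed genes, the 10 with the largest change in each direction among genes past the threshold (none passed), up to 4 members with the smallest p of each list described, and genes of the contamination checks. Which lists were described was decided after their values were seen.

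Alternatives were RLE scaling, DESeq2 1.42.0 with independent filtering as by default, limma-voom with sample quality weights, no filter, a filter at 1 CPM, a minimum log2 fold change of 1, counts thinned to the smallest library, leaving out globin, immunoglobulin, ribosomal RNA and mitochondrial genes, fitting only the groups compared, and leaving out each library in turn. Chosen after seeing the data were DESeq2 with filtering set for 0.05, and leaving out the 4 libraries in which exocrine pancreas genes took over 0.05% of counts. The planned list of progression genes was empty because no gene passed the threshold, so the 200 genes with the smallest p in each direction were used instead, also chosen after seeing the data. Each count was set against 100 splits of the same libraries, the real one included. The quasi-likelihood steps were tested on simulated data in which 200 genes had known changes. Among genes changed 4-fold, 97% were recovered for day 20 against day 13, 88.1% for responders and 92.5% for non-responders against isotype, 82.1% for responders against non-responders, and 94.0% for all treated mice against isotype; among those changed 2-fold, 47.8%, 28.4%, 38.8%, 28.4% and 59.7%. The simulation drew genes independently of each other, changed only genes at a mean of at least 2 CPM, and did not model mice that stand apart. Recovery in the real data may therefore be lower. Gp6, higher by log2 2.80 at day 20 than at day 13, had an adjusted p of 0.16 in the edgeR test. Figures were drawn with matplotlib 3.10.9.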

Results

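Spleen transcriptomes of 28 MPLW508A mice, a model of primary myelofibrosis, a blood cancer with megakaryocyte expansion and scarring, were compared in 2 settings. The first compared isotype-treated mice at days 20 (n = 5) and 13 (n = 5), which the series' design text names progression. No mice free of the disease were profiled at these days. Change with disease was therefore not told apart from other change over time in these transplanted mice. The second compared mice given 58A2, an antibody that blocks release of active TGF-β1 from the membrane protein GARP, with isotype-treated mice at day 34, separately for 5 mice labelled as responders, 5 labelled as non-responders, and both together, against 8 controls. Library totals lay between 21589253 and 25679424 counts. Mpl, which carries the modelled change, was measured at 1994 ± 431 CPM at day 13 (SD, n = 5), 1670 ± 611 at day 20 (SD, n = 5) and 915 ± 466 in isotype mice at day 34 (SD, n = 8), in tables scaled separately; reads of the transplanted construct and the endogenous gene were not told apart. In none of the 5 comparisons did a gene pass the edgeR quasi-likelihood test at an adjusted p of 0.05, so the groups of genes below are described by their lists.

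Between days 13 and 20, the megakaryocyte, B cell, T cell and mast cell lists were higher and the interferon-response list lower by camera with a preset correlation. None of these 5 lists passed with an estimated correlation (adjusted p 0.404 for each). Of 24 tested megakaryocyte and platelet genes, 18 rose when adjusted over the list alone and 0 when adjusted over all genes, with a median log2 fold change of 1.98. Gp6, the platelet collagen receptor, was higher by 2.80 ± 0.56 (log2, SE), Tubb1, the platelet β-tubulin, by 2.96 ± 0.63, and Ppbp, a platelet chemokine, by 2.53 ± 0.55. Pf4, platelet factor 4 (ENSMUSG00000029373, chromosome 5, 90772435 to 90773383, GRCm38, a protein-coding gene), stood at 168 ± 160 CPM at day 20 and 31.1 ± 9.17 at day 13 (SD, n = 5 each), with 446 CPM in day-20 mouse 21 and 32.1 to 134 in the other day-20 mice. Of 13 B cell genes 11 rose over the list alone, led by Pax5, the B-lineage transcription factor (chromosome 4, 44524757 to 44710487), by 4.99 ± 0.81 and Cd79a, part of the B cell receptor, by 2.79 ± 0.50. Pax5 was near the floor at day 13, at 0.14 ± 0.098 CPM, and 4.60 ± 4.42 CPM at day 20 (SD). Cd19 was 4.66 ± 4.12 CPM at day 20 and 0.43 ± 0.22 at day 13 (SD, n = 5 each), low levels in both. Of 19 T cell genes 14 rose over the list alone, including Lef1 (log2 3.65 ± 0.72) and Cd28 (log2 1.96 ± 0.47), and of 12 mast cell and basophil genes 10 did, including the basophil protease Mcpt8 (log2 1.49 ± 0.34). Lef1 and Cd28 were low, at 1.47 ± 1.24 and 1.85 ± 1.16 CPM at day 20. At day 13 they were 0.115 ± 0.072 and 0.469 ± 0.208 CPM (SD).

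Of 30 interferon-response genes, 7 fell when adjusted over the list alone and the list's median log2 fold change was −0.57. Fold changes were positive for 9 of the 30, of which 3 had an unadjusted p under 0.05 and none passed over the list alone, as the chemokine gene Cxcl9 (9.33 ± 6.79 CPM at day 20 and 3.75 ± 0.48 at day 13, SD). The antiviral synthetases Oas1a and Oas2 fell by 1.29 ± 0.27 and 1.70 ± 0.38 on the log2 scale (SE), and Mx2, a polymorphic pseudogene in GENCODE M21, by 1.46 ± 0.33. In the collagen and matrix list 3 of 32 genes rose over the list alone, namely Timp3, an inhibitor of matrix proteases, and the matrix proteoglycans Dcn and Lum. The fibrillar collagen genes did not pass: Col1a1 was 142 ± 55.4 CPM at day 20 and 200.1 ± 41.4 at day 13, and Col3a1 167 ± 53.8 and 171 ± 43.8 (SD, n = 5 each). Lrrc32, which encodes GARP (ENSMUSG00000090958, chromosome 7, 98489283 to 98502181), rose over its list alone from 10.1 ± 1.05 to 39.1 ± 35.6 CPM (SD, n = 5 each, 101 in day-20 mouse 21), as did Ikzf2. Tgfb1 was 275 ± 103 and 200.5 ± 46.2 CPM and did not pass. Foxp3 and Ifng were too low to be tested, with at most 31 and 4 counts in a day-20 library. All 24 neutrophil genes had positive fold changes, as Ctsg (log2 1.68 ± 0.48), and 24 of 25 erythroid and 30 of 30 cell cycle genes negative ones, but none of these members passed over its list alone.

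**Figure D1:**
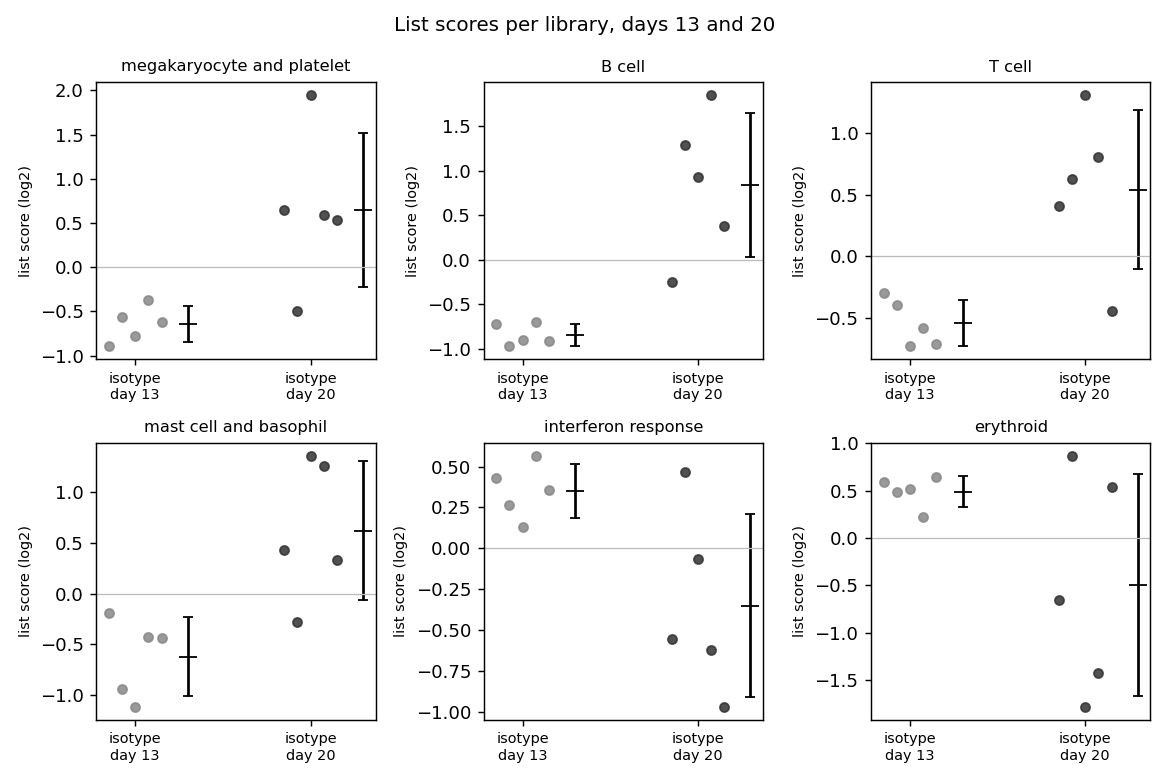
Score of 6 gene lists (y axis, mean over members of centred log2 CPM) in each isotype-treated mouse at days 13 and 20; points are mice, bars mean and SD. Megakaryocyte scores at day 20 spread more widely than at day 13, and 1 of 5 mice lay within the day-13 range.

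Camera with its preset correlation placed 24 of 28 lists past the threshold, 18 higher and 6 lower, of which none passed with an estimated correlation (lowest adjusted p 0.404), and 2 of 100 splits of the mice, the real one included, gave as many. The other splits gave a median of 13 lists, so many lists also passed without the real grouping. Camera with its preset correlation gave adjusted p of 3e-10 for megakaryocyte, 8.46e-10 for B cell, 3.2e-08 for T cell, 1.58e-06 for mast cell and basophil and 3.2e-08 for interferon-response genes. In an exact permutation test of the score per mouse, the lowest adjusted p was 0.0888, shared by 10 lists: megakaryocyte, B cell, T cell, mast cell, regulatory T cell and GARP, stromal, endothelial, stem cell, JAK-STAT target and mitochondrial. It was 0.111 for interferon-response genes. The smallest p this test can give with 5 and 5 mice is 0.00794. A single list could therefore not pass after adjustment. Mitochondrially encoded genes, a sign of RNA quality, were higher at day 20 in 12 of 13, with a median log2 fold change of 0.408 (camera adjusted p 0.00773, and 0.404 with an estimated correlation). At an unadjusted p under 0.05 the edgeR test had 3215 of 15463 genes, 2593 of them higher, against 773 by chance. DESeq2 called 665 genes higher and 49 lower and limma-voom with quality weights 337 and 86. Without day-20 mouse 19 the edgeR test called 107 genes higher and 30 lower, and the interferon count became 18, while it was 4 without day-13 mouse 1 and 17 with limma-voom. The T cell count was 7 without day-20 mouse 19 or 21 and 8 without day-13 mouse 3 or day-20 mouse 16 or 22, and with the stricter filter it was 7 and the mast cell and basophil count 6. The regulatory T cell and GARP count was 5 with no filter or DESeq2, and the matrix count was 0 without day-13 mouse 1, 3 or 5 and 1 without day-13 mouse 4 or day-20 mouse 16, 21 or 22. Day-20 mouse 21 stood apart, with Pf4 at 446 CPM and Lrrc32 at 101 CPM.

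At day 34, the megakaryocyte and neutrophil lists were lower, and the interferon-response list higher, in the 5 responders than in the 8 isotype mice by camera with a preset correlation. None of the 3 lists passed with an estimated correlation (adjusted p 0.21 for each). Pf4 was 19.6 ± 33.1 CPM in responders (SD, n = 5) and 159 ± 133 in isotype mice (SD, n = 8), and 4 of 5 responders were at or under 6.36 CPM, as was 1 of 8 isotype mice, at 2.95. Of 24 megakaryocyte genes, 16 fell when adjusted over the list alone and 0 over all genes, with a median log2 fold change of −1.82; Nrgn fell by 2.41 ± 0.82, the platelet glycoprotein gene Gp9 by 1.76 ± 0.61 and Vwf by 1.66 ± 0.57 on the log2 scale (SE). Itga2b, a megakaryocyte integrin, was 249.6 ± 75.6 and 263 ± 98.7 CPM and did not differ beyond its spread. Of 24 neutrophil genes all had negative fold changes and 11 fell over the list alone, with a median of −2.05; the protease gene Mmp8 fell by 2.09 ± 0.65 and Retnlg by 2.22 ± 0.72. S100a8, an abundant neutrophil transcript, was 255 ± 264 CPM in responders and 1069 ± 685 in isotype mice.

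Of 30 interferon-response genes 6 rose over the list alone, among them Gbp2 (127 ± 72.2 against 32.0 ± 33.1 CPM, SD), Irf7 (269 ± 75.8 against 129 ± 75.5) and Cd274, which encodes PD-L1 (48.7 ± 33.8 against 15.7 ± 14.2). Of 12 plasma cell genes 3, Mzb1, Tnfrsf17 and Jchain, rose over the list alone and 3 had negative fold changes, with a median of 0.362. Camera's adjusted p for this list was 0.00205, and 0.485 with an estimated correlation. Jchain, the joining chain of secreted antibody, rose to 141 ± 76.4 from 45.6 ± 29.4 CPM. Tnfrsf17 was near the floor, at 0.484 ± 0.369 CPM in responders and 0.118 ± 0.0967 in isotype mice. Mzb1 was also low, at 1.58 ± 1.35 and 0.43 ± 0.259 CPM. In the immediate early list 5 of 18 genes rose over the list alone, as Junb (log2 0.93 ± 0.25) and Fos (log2 0.96 ± 0.28); camera's adjusted p was 1.91e-05, and 0.21 with an estimated correlation. The mast cell protease gene Cpa3 rose by 3.62 ± 0.91, with 1 responder at 320 CPM; its call ended without that mouse. Globin genes were higher without passing, Hbb-bt by 1.25 ± 0.48 (log2, SE), in an erythroid list with a camera adjusted p of 9.69e-10, and 0.485 with an estimated correlation. Lrrc32 was 11.4 ± 6.13 and 29.8 ± 26.5 CPM, Tgfb1 155 ± 11.7 and 204 ± 61.6, Foxp3 2.29 ± 2.11 and 1.05 ± 0.92, Cd8a 5.76 ± 3.05 and 4.36 ± 3.92, Gzmb 3.59 ± 2.19 and 3.24 ± 3.20, Col1a1 90.1 ± 11.5 and 129 ± 74.6, and Lox 9.76 ± 5.26 and 17.4 ± 10.8 CPM in responders and isotype mice, none past the test. No member of the cytotoxic lymphocyte, regulatory T cell and GARP, TGF-β response or collagen lists passed over its list alone.

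**Figure D2:**
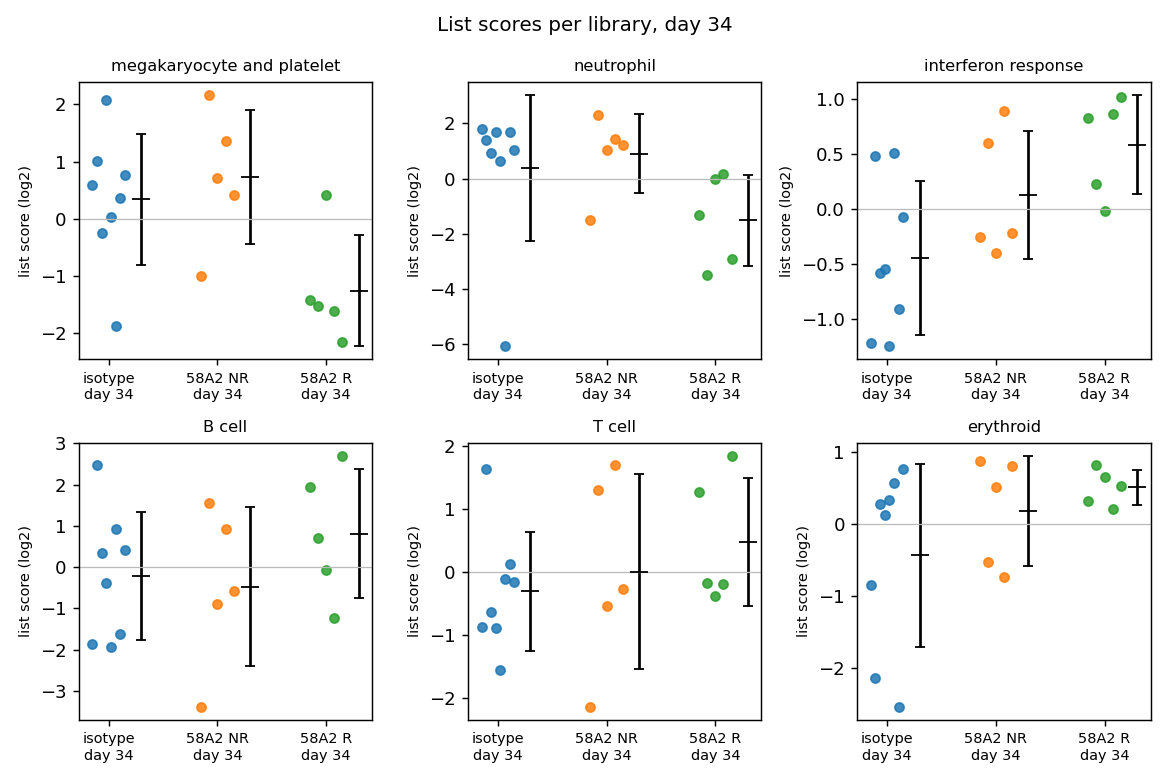
Score of 6 gene lists (y axis, mean over members of centred log2 CPM) in each day-34 mouse given isotype antibody (n = 8) or 58A2, non-responders (NR, n = 5) and responders (R, n = 5); points are mice, bars mean and SD. Groups overlap in each list, and 1 isotype mouse lies with or below the responders in the megakaryocyte and neutrophil scores.

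**Figure D3:**
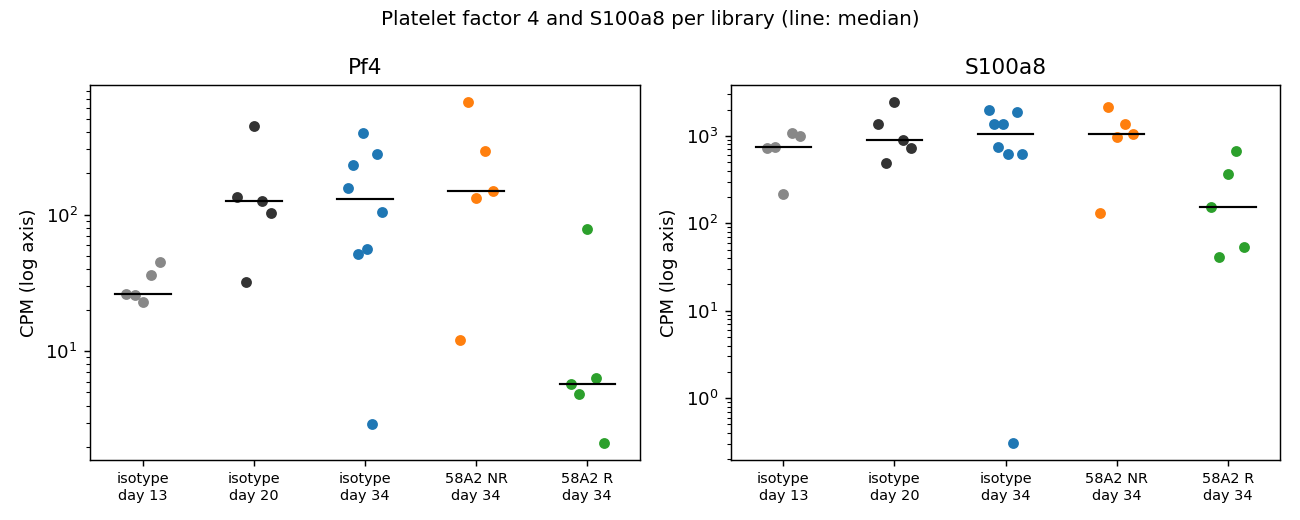
Pf4 and S100a8 in CPM (log axis) in each mouse of the 5 groups, days 13 and 20 scaled apart from day 34; NR and R are 58A2 non-responders and responders, and lines are medians. Pf4 lies at or under 6.36 CPM in 4 of 5 responders and at 2.95 CPM in 1 isotype mouse.

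Camera placed 16 of 29 lists past the threshold for responders, with adjusted p of 1.98e-14 for megakaryocyte, 1.23e-23 for neutrophil and 1.81e-18 for interferon-response genes, and none with an estimated correlation (lowest adjusted p 0.21). Other splits of the same mice gave a median of 12 lists and at most 22. The edgeR test had 1124 genes at an unadjusted p under 0.05 against 857 by chance, DESeq2 called 9 genes higher and 1 lower, and limma-voom none. The megakaryocyte count became 0 without isotype mouse 8, 17 or 28 or responder 10, 19, 29 or 31. The neutrophil count became 0 without isotype mouse 2 or 17 or responder 10, 19 or 31, 7 without isotype mouse 8, 26 or 28, 24 without isotype mouse 23 and 23 without responder 29. The interferon count became 0 without isotype mouse 2, 11, 17, 20 or 26 or responder 10, 29 or 31, 11 without isotype mouse 8 and 14 without isotype mouse 23. The plasma cell count became 0 without responder 31, and the immediate early count 0 without isotype mouse 2 or responder 31, 1 without isotype mouse 20 or responder 10, 2 without isotype mouse 11 or 26 or responder 29 and 3 without isotype mouse 8 or responder 19. The mast cell and basophil count, 1 with all mice, became 3 without isotype mouse 8 or responder 19, 27, 29 or 31, 4 without isotype mouse 23 and 0 without responder 10. All of these counts were 0 without the 4 libraries that held pancreatic transcripts. With limma-voom the megakaryocyte, neutrophil and mast cell counts were 0 and the interferon count 24, with no filter the megakaryocyte and neutrophil counts were 0, with DESeq2 the neutrophil count was 22 and the mast cell count 2, and with only the groups compared the interferon count was 0 and the immediate early count 3.

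In non-responders against isotype mice, no member of any list passed over its list alone. Pf4 was 249.7 ± 253 CPM in non-responders (SD, n = 5), S100a8 1127 ± 718, Lrrc32 38.2 ± 32.3 and Col1a1 117 ± 58.9, beside 159 ± 133, 1069 ± 685, 29.8 ± 26.5 and 129 ± 74.6 in isotype mice (SD, n = 8). Globin genes were higher without passing: Hba-a1 was 35730 ± 21500 and 16870 ± 12700 CPM, and Hbb-bt was higher by 1.11 ± 0.48 (log2, SE), beside 1.25 ± 0.48 in responders. Of 25 erythroid genes 21 had positive fold changes, with a camera adjusted p of 1.77e-06, and 0.83 with an estimated correlation; without the 4 libraries that held pancreatic transcripts the list turned lower, with an adjusted p of 0.647. Among interferon-response genes 29 of 30 had positive fold changes, as Isg15 (log2 0.82 ± 0.45) and Stat1 (log2 0.46 ± 0.25), and all 24 megakaryocyte genes did, with a median of 0.44. In the plasma cell list Jchain was 126 ± 107 CPM, against 45.6 ± 29.4 in isotype mice. Tnfrsf17 was higher by 1.62 ± 0.60 (log2, SE) without passing, at the low levels of 0.38 ± 0.191 and 0.118 ± 0.0967 CPM. Camera placed 13 lists past the threshold, all higher, with the lowest adjusted p at 0.83 with an estimated correlation. The edgeR test had 286 genes at an unadjusted p under 0.05, fewer than the 857 chance gives, and DESeq2 and limma-voom called 0.

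In responders compared directly with non-responders, the megakaryocyte and neutrophil lists were lower by camera with a preset correlation. Neither passed with an estimated correlation (adjusted p 0.166 and 0.191). Of 24 megakaryocyte genes, 19 fell over the list alone in responders, with a median log2 fold change of −2.27. The log2 fold change was −3.67 ± 1.16 for Pf4, −2.99 ± 0.88 for Nrgn and −2.32 ± 0.66 for Gp9 (SE). Of 24 neutrophil genes, 7 fell over the list alone and 24 had negative fold changes, as Retnlg (29.4 ± 18.5 against 138 ± 72.8 CPM) and Mmp8 (14.0 ± 8.57 against 53.2 ± 30.3). The mast cell and basophil list moved both ways: the mast cell genes Cpa3 and Mcpt4 were among 3 that rose over the list alone, and the basophil gene Prss34 and the histidine decarboxylase gene Hdc among 3 that fell. B cell genes were higher in 17 of 18 without a member passing, as Cr2 (log2 1.61 ± 0.91). Camera's adjusted p was 4.9e-25 for megakaryocyte, 2.52e-31 for neutrophil and 3.13e-06 for B cell genes, and 0.166, 0.191 and 0.66 with an estimated correlation. In the exact permutation test of the score 2 lists had an unadjusted p under 0.05. The megakaryocyte list was among them, at 0.0159, adjusted 0.231 over 29 lists. With 5 and 5 mice a single list could not pass this test after adjustment, as its smallest p is 0.00794. The edgeR test had 918 genes at an unadjusted p under 0.05 against 857 by chance, and DESeq2 and limma-voom called 0. The count of lower megakaryocyte genes became 0 without non-responder 4 or responder 31 and 12 without responder 10. The neutrophil count became 0 without non-responder 4, 13, 16 or 25 or responder 10, 19 or 31, 24 without non-responder 1, 21 without responder 27 and 23 without responder 29. Both mast cell and basophil counts became 0 without non-responder 4, 13, 16 or 25 or responder 10, and without responder 19, 29 or 31 they became 1 higher and 0 lower. With limma-voom the megakaryocyte, neutrophil and mast cell counts were all 0. The neutrophil count was 20 with RLE scaling or without globin, immunoglobulin, ribosomal RNA and mitochondrial genes, 22 with DESeq2 and 23 with only the groups compared, and 0 with no filter. The mast cell and basophil counts were 0 with no filter or only the groups compared. Without the 4 libraries that held pancreatic transcripts the neutrophil and the mast cell and basophil counts were 0.

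With both treated groups together, 3 of 12 plasma cell genes rose over the list alone against isotype mice, Jchain, Tnfrsf17 and Mzb1, and 3 had negative fold changes, with a median of 0.369. Camera's adjusted p was 0.000374, and 0.573 with an estimated correlation. Jchain was 134 ± 88.1 CPM (SD, n = 10) against 45.6 ± 29.4 (SD, n = 8). Tnfrsf17 was near the floor, at 0.432 ± 0.283 against 0.118 ± 0.0967 CPM. Fos rose by 0.90 ± 0.24 (log2, SE). All 30 interferon-response genes had positive fold changes, with Isg15 at 1015 ± 348 and 471 ± 360 CPM and Gbp2 at 83.0 ± 67.5 and 32.0 ± 33.1 CPM, but none passed over the list alone; camera's adjusted p was 1.64e-18, and 0.343 with an estimated correlation. Pf4 was 135 ± 209 CPM and S100a8 691 ± 687 CPM in treated mice, beside the isotype values given above. This comparison does not depend on the response label. Camera placed 16 of 29 lists past the threshold, and none passed with an estimated correlation (lowest adjusted p 0.343). The edgeR test had 530 genes at an unadjusted p under 0.05 against 857 by chance, and DESeq2 and limma-voom called 0. The plasma cell count became 0 without responder 31 and 1 with thinned counts, and the call of Fos ended without isotype mouse 2, 11 or 20, non-responder 16 or responder 10 or 31. The immediate early count, 1 with all mice, was 3 with no filter, with DESeq2 or without responder 27, 4 without isotype mouse 23, and 0 without the 4 libraries that held pancreatic transcripts.

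**Figure D4:**
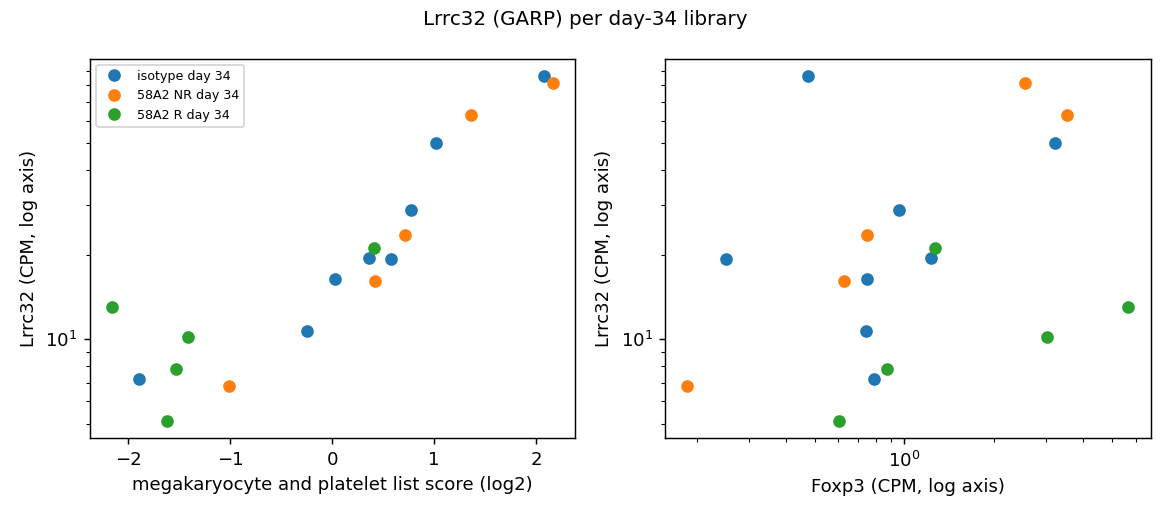
Lrrc32 in CPM in the day-34 mice given isotype antibody (n = 8) or 58A2, non-responders (NR, n = 5) and responders (R, n = 5), against the megakaryocyte and platelet score and against Foxp3; each point is a mouse. Lrrc32 was highest, at 86.6 CPM, in an isotype mouse with a megakaryocyte score of 2.07.

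The 200 genes with the smallest p in each direction between days 13 and 20, none of which passed the adjusted threshold, were followed into day 34. Of those higher at day 20, 196 were tested at day 34, and their median log2 fold change was −0.98 in responders and 0.32 in non-responders against isotype, and −1.20 in responders against non-responders. The unadjusted p of these shifts was 1.4e-22, 0.00332 and 1.31e-34 by camera with a preset correlation. It was 0.133, 0.639 and 0.067 with an estimated correlation, and 0.178, 0.673 and 0.121 by fry. Of those lower at day 20, 192 were tested, and their medians in the same order were smaller, at 0.146, −0.021 and 0.18. Their unadjusted p was 1.54e-10, 0.886 and 2.15e-10 by camera with a preset correlation. It was 0.106, 0.97 and 0.11 with an estimated correlation, and 0.0496, 0.856 and 0.105 by fry. Whether the responder shifts passed thus depended on the correlation setting. Across 15054 genes, which are not independent replicates, the progression fold changes had a Pearson r of −0.36 with those of responders, 0.24 with those of non-responders and −0.50 with those of responders against non-responders. With 1 mouse left out the r was −0.508 to −0.136 for responders (−0.136 without isotype mouse 8 and −0.224 without responder 19) and −0.621 to −0.246 for responders against non-responders (−0.246 without non-responder 16 and −0.307 without 4). For non-responders it turned to −0.147 without non-responder 4 and −0.169 without 16, was 0.113 without isotype mouse 23, 0.144 without isotype mouse 11, 0.463 without isotype mouse 8, 0.435 without non-responder 1 and 0.462 without non-responder 25, and was −0.00499 over genes with a progression log2 fold change of at least 1. Of 100 splits of the day-34 mice, 49, 80 and 43 gave an r at least as far from 0. The responder and non-responder effects against the same 8 isotype mice had a Pearson r of 0.378 and a covariance of 0.0584 across genes, beside 0.382 and 0.0611 for simulated unchanged groups, and a mean r of 0.00312 over 70 splits of the controls 4 and 4, so no shared effect was detectable. The r over these splits ran from −0.479 to 0.456, and the simulation drew genes independently. A shared effect of moderate size could therefore have been missed.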

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

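The tests of erythroid dilution, of the spread of pancreatic transcripts over groups and of the setting without the 4 libraries that held them were chosen after the results were seen. Of 302 combinations of a gene or other measure with a group, 34 had a mouse far from its group, where a rate of 1 in 20 gives about 15. That rate assumes independent, normally distributed values. Several of the genes moved together in the same mouse, so the excess over 15 decides nothing.

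Megakaryocyte and neutrophil genes were lower in responders than in isotype mice at day 34, with a median log2 fold change of −2.05 over both lists. With any 1 library left out the median stayed at −1.78 or lower, and without the 4 libraries with pancreatic transcripts it was −1.90, which argues against a single library or pancreatic tissue as the whole cause of the shift. The counts of genes past the list-alone threshold still became 0 without those 4 libraries. Dilution by erythroid RNA would lower every other cell type alike. The mean score of the 11 other non-erythroid cell type lists differed by 0.281 (95% interval −0.482 to 1.04), against −1.75 for the mean of the megakaryocyte and neutrophil scores. These scores use TMM-scaled library sizes, which offset a fall shared by most genes, so the 0.281 cannot decide on dilution. Scaling largely cancels in the gap between these means, which was −2.03 (95% interval −4.07 to 0.00324). Dilution was therefore not excluded. Among the 11 lists were the monocyte (0.0563, −0.624 to 0.737), endothelial (0.0774, −0.497 to 0.652) and stem cell scores (−0.146, −0.598 to 0.306), while the intervals of the B cell (1.02, −1 to 3.05) and mast cell scores (−0.152, −1.82 to 1.52) were wide. The shift itself was uncertain with 5 and 8 mice: its exact two-sided permutation p was 0.08, that of its gap to the 11 lists 0.0668 and that of its gap to the B and T cell lists 0.0707. The response itself, which the labels define by an outcome not described, stays open as a biological explanation and was not tested.

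Exocrine pancreas genes took 0.245% of counts in isotype mouse 26, 0.0706% in non-responder 13, 0.0914% in non-responder 25 and 0.278% in responder 10, against at most 0.014% in the other day-34 libraries; isotype mouse 26 and responder 10 lay far from their groups. The log2 CPM of the 19 exocrine genes tested had a lowest Pearson r of 0.904 across genes, which are not independent replicates, between any pair of these libraries. Such an r follows which genes are abundant, does not test a constant ratio, and was not computed for the other libraries. Pancreatic tissue next to the spleen is a candidate source, which was not tested further. The 4 libraries lay in all 3 groups (Fisher's exact p 0.771), so they were not confined to 1 group. With only 4 such libraries, a weaker link with the group was not excluded.

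At day 13, Mx2 in mouse 4 (14.5 CPM) and the share of mitochondrial counts in mouse 5 (0.657%) lay far from the group. At day 20, mouse 21 lay far above the others in Lrrc32 (101 CPM), Pf4 (446), Gp6 (48.2), Trpc6 (33.7), Tubb1 (198), Ppbp (757), Csf3r (177), Lat (70.3) and Timp3 (334). Among isotype mice at day 34, mouse 8 stood far out in Foxp3 (3.21 CPM), Cd8a (13.1), Cd19 (52.7) and Derl3 (2.64), mouse 17 in Itga2b (486) and Timp3 (211), and mouse 23 in Mmp8 (1.67), Gbp2 (108) and Ifit1 (181). Non-responder 1 stood far out in Oasl1 (30.2 CPM). Responder 27 did so in Pf4 (78.7 CPM), Nrgn (19.3), Gp9 (20.8), Vwf (58.7) and Prss34 (19.5), responder 10 in Cpa3 (320), Mcpt4 (91.7) and Tpsb2 (79.8), and responder 31 in Egr1 (1200), Ctla4 (9.63) and Dusp1 (87.0).

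Responders and non-responders differed by camera with the preset correlation in 11 lists, none of which passed with an estimated correlation (lowest adjusted p 0.166). The groups are defined by an outcome, so a difference between the mice before treatment was not told apart from a differing effect of 58A2. The adjusted p was 4.9e-25 for megakaryocyte, 2.52e-31 for neutrophil, 0.00195 for monocyte and macrophage, 0.00974 for stem and progenitor, 3.13e-06 for inflammatory cytokine and 1.02e-05 for adipose genes, all lower in responders. It was 0.0408 for erythroid, 3.13e-06 for B cell, 4.74e-05 for interferon-response, 6.23e-07 for cell cycle and 0.0123 for immediate early genes, all higher in responders.

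Splits of the mice, 100 in each case with the real one included, gave a result as large in under 5 in 100 for 1 of the 14 counts and correlations in which this was possible, the number of lists between days 20 and 13. There 2 splits gave as many as the real 24, the highest other giving 25. A single such result among 14 is near what chance gives, so over the 14 together chance was not excluded. No list of that comparison passed with an estimated correlation (lowest adjusted p 0.404), with fry (0.112) or with the exact permutation of scores (0.0888). For genes at an unadjusted p under 0.05 between days 20 and 13, 7 splits gave as many as the real 3215, the highest other 4786, so chance was not excluded. For responders against isotype 23 splits gave as many as the real 1124 genes (highest other 4580) and 30 as many as 16 lists (highest other 22). For non-responders 69 gave as many as 286 genes (highest other 7206) and 63 as many as 13 lists (highest other 25, median 15). For responders against non-responders 32 gave as many as 918 genes (highest other 4931) and 83 as many as 11 lists (highest other 23, median 16). For all treated mice 48 gave as many as 530 genes (highest other 5786) and 38 as many as 16 lists (highest other 24, median 13). A correlation with the progression fold changes as far from 0 was given by 49 splits for −0.358 (highest other 0.766), 80 for 0.239 (0.804), 43 for −0.50 (0.808) and 76 for −0.157 (0.76), in the same order of comparisons. For genes past the edgeR threshold the real count was 0 in each comparison, which all 100 splits reach, so these counts decide nothing. Their highest others were 294, 907, 4943, 57 and 2237, with a median of 0 in each. Single splits with several times the real count, as 7206 genes at an unadjusted p under 0.05 beside 286, point to structure among the mice, which was not tested further.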

How the results depend on the processing

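No paired analysis was possible because the groups compared share no animal numbers. DESeq2 with filtering set for 0.05, the setting without the 4 libraries with pancreatic transcripts and the exact permutation of list scores were chosen after the results were seen. Causes were not tested unless stated. At these depths 1 CPM stood for 17.9 to 33.3 counts.

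The edgeR test called 0 genes in all 5 comparisons with RLE scaling, the stricter filter, a minimum log2 fold change of 1, thinned counts, and without globin, immunoglobulin, ribosomal RNA and mitochondrial genes. For day 20 against day 13, 5 genes were higher and 1 lower with no filter, 665 and 49 with DESeq2, 663 and 50 with its filtering set for 0.05, and 337 and 86 with limma-voom. Leaving out single mice gave 0 to 107 higher and 0 to 30 lower, the highest of both without day-20 mouse 19. For responders against isotype, DESeq2 called 9 higher and 1 lower, or 7 and 1 with filtering set for 0.05, and leaving out single mice gave 0 to 1 higher, the 1 without isotype mouse 23.

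The number of lists past the threshold was 0 in all 5 comparisons with an estimated correlation, with fry and with the exact permutation of scores. For responders against non-responders it was 19 without the libraries with pancreatic transcripts. Over single mice left out it was 19 to 25 for day 20 against day 13, 13 to 18 for responders, 8 to 19 for non-responders (8 without non-responder 4), 11 to 15 for responders against non-responders and 11 to 19 for all treated mice. The exact permutation could not pass a single list on its own with 5 and 5 mice.

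Some list directions turned. Without the libraries with pancreatic transcripts the adjusted p was 0.0221 for ribosomal protein genes in responders, 0.647 for erythroid and 0.188 for heme synthesis genes in non-responders, and 0.684 for cell cycle genes in all treated mice. Over single mice left out, the adjusted p for monocyte genes between days 20 and 13 was 0.000737 to 0.544, turning without day-20 mouse 21. For exocrine pancreas genes in responders it was 0.0137 to 0.953, turning without responder 10. In non-responders it was 0.00029 to 0.568 for neutrophil genes, turning without isotype mouse 23 (0.00639), 5.39e-07 to 0.828 for T cell, 0.000249 to 0.955 for T cell inhibitory receptor and 0.000228 to 0.977 for cell cycle genes, these 3 turning without non-responder 16 (0.828, 0.955 and 0.00538), and 0.000137 to 0.943 for exocrine pancreas genes, turning without non-responder 25 (0.845). For cell cycle genes in all treated mice it was 1.01e-05 to 0.58, turning without isotype mouse 8.

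The correlation with the progression fold changes, restricted to genes with a progression log2 fold change of at least 1, was −0.00499 for non-responders, which turned its sign, −0.388 for responders against non-responders and −0.31 for all treated mice. Over single mice left out it was −0.508 to −0.136 for responders, −0.169 to 0.463 for non-responders (−0.147 without non-responder 4 and −0.169 without 16), −0.621 to −0.246 for responders against non-responders and −0.344 to 0.148 for all treated mice (0.148 without isotype mouse 8). The correlation of responder and non-responder effects had a mean of 0.00312 with the controls split. Of the other list tests 2563 stayed on the same side of the threshold, 158 moved past it and 328 lost it. Direction was compared only where the main or the alternative test passed, so turns of sign among other tests were not counted. No named gene passed in the main test, and 3990 results stayed short of the threshold while 102 moved past it. Of the 102, 29 did so with DESeq2, 29 with its filtering set for 0.05, 26 with limma-voom, 17 without day-20 mouse 19 and 1 with no filter. Of list-alone counts 349 equalled the main count or lay within a fixed fold of it, and 212 moved further.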

Other observations

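The tests of Lrrc32 against the megakaryocyte score and Foxp3 were chosen after the results were seen, as were the genes named in the next 2 paragraphs.

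Between days 13 and 20, vessel, stem cell and inflammatory genes were higher in part. Of 19 endothelial genes 5 rose when adjusted over the list alone, including Vwf, Tek and Lyve1. Vwf is also in the megakaryocyte and platelet list, so it is no separate sign of vessel genes. Of 18 stem and progenitor genes 5 rose, including Angpt1, Cd34 and Meis1, and of 21 inflammatory genes 2, the interleukin-1 genes Il1a and Il1b. Of 5 adipose genes tested 3 rose, Car3, Lpl and Cfd. Of 14 cytotoxic genes 1 rose, Cst7, and of 18 dendritic cell genes Cd209a rose and Bst2 fell. In the immediate early and heat shock list Egr2 and Egr3 rose while the heat shock genes Hspa1b, Hsph1 and Dnajb1 fell. The counts depended on single mice: the endothelial count was 0 without day-13 mouse 1, 2, 3 or 5, 1 without day-20 mouse 22, 2 without day-20 mouse 21 and 11 without day-20 mouse 16, and the stem count 1 without day-13 mouse 3. The inflammatory count was 0 without day-13 mouse 1, 3 or 5 or day-20 mouse 22, and 4 without day-20 mouse 51. The adipose count was 0 without day-13 mouse 2, 3 or 5 or day-20 mouse 21 or 22, 1 without day-20 mouse 19, and 5 without day-20 mouse 51. The cytotoxic count was 0 without day-13 mouse 1, 2 or 3 or day-20 mouse 16, 21 or 22, 2 without day-20 mouse 19, 3 without day-13 mouse 4 or 5, and 8 without day-20 mouse 51. For dendritic cell genes the higher count was 0 without day-13 mouse 1 or 5 or day-20 mouse 22, 3 without day-13 mouse 4, 9 without day-20 mouse 19 and 10 without day-20 mouse 51, and the lower count 0 without day-13 mouse 1 or 5 or day-20 mouse 16 or 22. In the immediate early and heat shock list the higher count was 1 without day-13 mouse 1, 2, 3 or 5 or day-20 mouse 16, 21 or 22. Its lower count was 1 without day-13 mouse 3, 4 or 5 or day-20 mouse 21 or 22, 2 without day-13 mouse 1 or 2 or day-20 mouse 16, and 4 without day-20 mouse 51. By setting, the cytotoxic count was 0 with RLE scaling, 3 with no filter or limma-voom and 7 with DESeq2, the endothelial count 8 with no filter and 3 with the stricter filter, and the adipose count 1 with RLE scaling or thinned counts. The dendritic cell counts were 2 higher with no filter, 3 higher with DESeq2, 0 both ways with the stricter filter and 0 lower with limma-voom. The immediate early counts were 1 higher with no filter, and 0 higher and 1 lower with the stricter filter. No member passed over its list alone among monocyte (camera adjusted p 0.0414), red pulp macrophage (0.218), plasma cell (0.0345), T cell inhibitory receptor (0.111), TGF-β response (0.00207), stromal (0.00425), JAK-STAT target (0.115), heme synthesis (2.09e-05), ribosomal protein (1.92e-08), mitochondrial (0.00773) and sex-linked genes (0.428). With an estimated correlation the adjusted p of all 28 lists was 0.404 or higher.

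At day 34 the 13 red pulp macrophage genes, which handle iron from old red cells, all had positive fold changes in responders and in non-responders against isotype, with medians of 0.29 and 0.53. Camera's adjusted p was 0.0118 and 5.47e-06, and 0.611 and 0.83 with an estimated correlation. The 9 adipose genes tested had a median log2 fold change of −1 in responders and 0.48 in non-responders. The remaining lists had no member past the list-alone threshold at day 34. In responders against isotype camera's adjusted p was 7.07e-05 for T cell, 0.00031 for B cell, 7.07e-05 for heme synthesis and inflammatory, 0.0309 for stromal, 0.0455 for mitochondrial and for collagen, 0.0562 for T cell inhibitory receptor, 0.673 for endothelial, 0.763 for monocyte, 0.651 for dendritic cell and ribosomal protein, 0.185 for JAK-STAT target, 0.0688 for sex-linked and 0.673 for exocrine pancreas genes, of which none passed with an estimated correlation. That adjusted p was at least 0.485 for the first 4, 0.682 for stromal, 0.74 for mitochondrial and 0.767 for collagen genes. No liver gene was tested in either table. The mean and median differed in sign for monocyte and for regulatory T cell and GARP genes in responders, and camera's direction differed from a positive median for mast cell and basophil genes there. The mean and median also differed in sign for cell cycle genes in non-responders, for T cell inhibitory receptor and mitochondrial genes in responders against non-responders, and for regulatory T cell and GARP and stem cell genes in all treated mice. Camera's direction was lower beside a positive median for JAK-STAT target genes in non-responders, for mast cell and basophil, exocrine pancreas and mitochondrial genes in responders against non-responders, and for dendritic cell genes in all treated mice, and higher beside a negative median for stem cell genes there and for T cell inhibitory receptor genes in responders against non-responders. None of these lists passed camera in that comparison.

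A hypothesis is that Lrrc32 reads in these spleens may come largely from megakaryocytes and platelets, which carry GARP, as well as from regulatory T cells. Across the 18 day-34 mice, centred per group, Lrrc32 followed the megakaryocyte and platelet score with a Pearson r of 0.893 (permutation p 1e-05, the smallest these permutations can give, adjusted 4e-05 over 4 relations) and a Spearman rho of 0.87 (p 2e-05). The r was 0.854 without the 2 mice farthest from the median of the score. In the 8 isotype mice r was 0.938 (exact permutation p 0.000496, adjusted 0.000992) and rho 0.976 (exact p 0.000397), and r 0.943 without the 2 farthest mice. With Foxp3, r was 0.564 over the 18 mice (permutation p 0.0276, adjusted 0.0368) and rho 0.536 (p 0.0372), falling to 0.445 without the 2 farthest mice. In the 8 isotype mice r was 0.172 (exact permutation p 0.697) and rho 0.19 (exact p 0.665), and r −0.459 without the 2 farthest. Foxp3 levels were low, at 0.186 to 5.68 CPM, sorted cells were not measured, and the sources cannot be separated here.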
